A study of Rattus with 108 samples.

How the data were processed

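The series compares skin, muscle and dorsal root ganglia (DRG, the clusters of sensory neuron cell bodies beside the spinal cord) of rats after surgery. Lateral paw incision (LPI) stood for acute and skin/muscle incision and retraction (SMIR) for chronic postsurgical pain, per the series' design text. Tissue was taken at 0 day, 6 hours, 2 days and 10 days in both models, and also at 32 days in SMIR. There were 27 groups of 4 libraries, 108 libraries in all, from 36 rats. Per the labels' protocols, rats were perfused with saline, total RNA was isolated, and strand-specific TruSeq libraries were sequenced on an Illumina NovaSeq instrument. DRG came from different cervical levels in the 2 models. The extraction protocol also speaks of pooling RNA of several animals, while the labels number animals, so the p-values measure the spread between libraries of a group, whether these stand for rats or for pools.

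The authors deposited 6 tables of read counts per gene, 1 for each model and tissue, and 6 matching tables of FPKM values. Reads were processed with FastQC 0.11.2, STAR and StringTie, per the submitters' processing notes, which name the builds rn6 and hg38 without saying how each was used. Counting settings, annotation release and filters were not given in the sources used here. The deposited counts are whole numbers that were not normalized, and each table holds the same 32623 Ensembl rat genes. The deposited FPKM values served only to derive gene lengths from the ratio of CPM to FPKM. Genes sharing reads with near-identical copies could not be singled out, since the treatment of such reads by the authors was not given.

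Column names give model, time code, a rat number and tissue. The time code 1 names no time point of the labels and was taken as 6 hours by elimination. Columns were therefore assigned to groups and not to single labelled samples, and libraries are named by the rat number of their column. The rat numbers recur only in part between time points and are not the labels' replicate numbers. No column was left unassigned. Over 162 pairs of libraries within groups, the lowest chi-square per degree of freedom of the counts was 11.8, so no pair agreed within sampling noise.

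Gene names were not used. The files do not pair gene IDs with names, and the reference table of 47357 rat genes paired 0 of them with an Ensembl ID. The 28 gene lists (474 symbols) and the rule for named genes that had been fixed could therefore not be applied: the rule would have taken, per comparison, the 5 largest rises and 3 largest falls among genes with a symbol and separated groups, and up to 4 members of each list. Gene groups defined from the counts took their place and were chosen after the data were seen. Tissue-enriched genes had at least 5 CPM (counts scaled to library size) in a tissue and at least 8 times the level of each other tissue, after adding 0.1 CPM, in the 0 day libraries of both models. This gave 483 skin-enriched, 176 muscle-enriched and 899 DRG-enriched genes. The groups were chosen on 0 day libraries, which favours high 0 day values in the tissue of the name, so groups taken from the other model alone were tried as an alternative. Response groups were the genes changed at least 2-fold in a comparison of 1 model, with at least 20 genes, and were read in the other model, whose libraries are separate. The 4 IDs printed were chosen after the data were seen among genes of at least 10 counts in each of the 16 skin libraries at 0 day and 6 hours that changed the same way in both models. This rule replaced a first one, which had given genes without counts at 0 day, whose folds cannot be interpreted.

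Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, estimateDisp, glmQLFit with robust estimation and glmQLFTest, two-sided, with Benjamini-Hochberg adjusted p under 0.05. Each model and tissue was fitted with all of its time points, which share an estimate of the spread. The difference between models was the SMIR change minus the LPI change in a fit of both tables of a tissue. Changes are log2 fold changes. A gene is called higher or lower when it passed this test. Gene groups were tested with fry of limma 3.58.1 on voom values, since fry does not take the quasi-likelihood fit. Its directional p tests whether the genes of a group move, on balance, one way, and does not compare a group with other genes. Adjustment was over 99 tests for the tissue-enriched groups and over 273 tests for the response groups. Medians of groups were also computed with genes absent from all libraries of an arm held at a floor of 3 counts over the group. Shares of counts were compared with exact permutation tests, two-sided, adjusted over 84 tests. With 4 against 4 libraries the smallest exact p is 0.0286, which became 0.0923 after adjustment. Overlaps of called genes used one-sided Fisher exact tests, with n1 × n2 / N as the overlap of independent lists. These tests take genes as independent, which they are not, and the tissues of a model come from the same rats. Their p-values therefore do not measure replication across animals.

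A gene-length trend was computed per library as Spearman's rho between gene length and log2 CPM centred over the libraries of a table. Between 88.8% and 91.6% of the tested genes of a table had a length. Alternatives fixed before the data were examined were size factors of DESeq2 (RLE), no filter on low counts, DESeq2 1.42.0, fits of only the groups compared, leaving out each library, and, for overlaps, a threshold of at least 2-fold. Alternatives added later were the length trend as a covariate, only LPI DRG libraries with a trend above 0, DRG libraries with at most 1% of counts in muscle-enriched genes, LPI muscle without 6 genes that rose and fell together (lowest pairwise r 0.995 across libraries), the number of the column as a block, only the 4 groups compared for the difference between models, and settings of the group tests.

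Library totals ran from 19080096 to 41654479 counts. The fits were tested on simulated data, drawn from the means and library sizes of the real samples with 200 genes changed by 1.5-fold, 2-fold or 4-fold. False calls numbered at most 7 among 15781 to 17369 genes run. Each gene was drawn independently, with no length trend, tissue admixture or other structure shared by the genes of a library. The number of false calls therefore does not cover calls that such structure brings in the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.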

Results

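Gene expression was measured by RNA sequencing in incised skin, muscle and DRG of rats after paw incision (LPI, acute) or skin/muscle incision and retraction (SMIR, chronic). Each of the 27 groups held 4 libraries. Total counts per library ran from 19080096 to 31620865 in LPI skin, from 21792696 to 30355655 in LPI muscle and from 21371113 to 26814368 in LPI DRG. In SMIR they ran from 25249730 to 37482675 in skin, from 29218629 to 41654479 in muscle and from 28015360 to 36223069 in DRG. Depth therefore differed between the models, and its effect on the number of calls was not tested.

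In skin after paw incision 8797 genes changed at 6 hours, 6754 at 2 days and 93 at 10 days. At 6 hours 4371 genes were higher and 4426 lower, with a median absolute log2 change of 0.97 among them, and at 2 days 3512 were higher and 3242 lower, with a median of 0.89. The DRG-enriched genes fell on balance at 6 hours, with a median log2 change of −0.84, 57 members higher and 155 lower among 448 tested (fry adjusted p = 0.0104), while their share of counts went the other way, 0.351% ± 0.0307 (SD, n = 4) against 0.267% ± 0.0241 at 0 day (exact permutation p = 0.0286, adjusted 0.0923). Of the 483 skin-enriched genes, 106 were higher and 208 lower at 6 hours and 107 higher and 183 lower at 2 days, and neither shift passed as a group (adjusted p = 0.209 and 0.627). The gene-length trend of the libraries moved with time, from 0.055 to 0.107 at 0 day to −0.123 to −0.022 at 6 hours and −0.193 to −0.082 at 2 days. With it as a covariate 8150 genes were called at 6 hours and 4167 at 2 days, and the DRG-enriched genes still passed at 6 hours (adjusted p = 0.0325). The ranges of the trend at both times did not overlap with that of 0 day, so this fit does not fully separate trend from time. At 10 days 52 genes were higher and 41 lower. DRG-enriched genes rose slightly on balance at that time (median 0.36, 3 higher and 0 lower, adjusted p = 0.0467, 0.0749 with no filter on low counts and 0.0760 with the length covariate). The count of changed genes, 93, moved when any of the 8 libraries was left out: it was 0 without rat 1, 2 or 4 at 0 day or rat 5 at 10 days, 2 without rat 6 at 10 days, 284 without rat 3 at 0 day, 428 without rat 4 at 10 days and 652 without rat 7 at 10 days. DESeq2 called 874 genes, a fit of these 8 libraries alone called 2, and the length covariate gave 213.

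In skin of the SMIR incision 10673 genes changed at 6 hours, 8930 at 2 days and 5428 at 10 days. Of the genes tested, 5301 were higher and 5372 lower at 6 hours, 4856 higher and 4074 lower at 2 days, and 3196 higher and 2232 lower at 10 days, with median absolute log2 changes of 1.05, 0.87 and 0.77. DRG-enriched genes fell at 6 hours (median log2 change −0.77, 94 higher and 248 lower of 610, adjusted p = 0.00165) and at 2 days (median −0.78, 70 higher and 217 lower, adjusted p = 0.00116), although their share of counts was 0.414% and 0.417% at these times against 0.412% at 0 day. The gene-length trend ran from 0.075 to 0.121 at 0 day, 0.001 to 0.061 at 6 hours and −0.280 to −0.167 at 2 days. With it as a covariate 10066 genes were called at 6 hours, but 462 at 2 days, where the median log2 change of the called genes went from 0.87 (median SE 0.18) to 0.53 (SE 0.39), and the DRG-enriched genes passed at 6 hours (adjusted p = 7.90e-04) but not at 2 days (adjusted p = 0.244). At 2 days trend and time go together, so the 2 cannot be separated there. At 6 hours the range of the trend did not overlap with that of 0 day either, so the calls kept do not fully separate them. Skin-enriched genes had 193 members higher and 105 lower at 2 days, which was not a shift as a group (adjusted p = 0.412). Their share of counts was 14.6% ± 2.00 (SD, n = 4) at 2 days against 10.2% ± 0.480 at 0 day, an exact permutation p of 0.0286 that became 0.0923 after adjustment. At 32 days 525 genes were higher and 91 lower, with a median absolute log2 change of 0.50. Between 10 and 32 days 2139 genes were higher and 1943 lower at 32 days, 141 of the skin-enriched genes among the former and 8 among the latter (group adjusted p = 0.209). The 32-day count of 616 was 86 without rat 1, 386 without rat 2, 145 without rat 3 and 170 without rat 4 of 0 day, 311 without rat 1 and 1425 without rat 3 of 32 days. It was 1302 with DESeq2, 350 with no filter on low counts, 113 with the length covariate and 0 when only the 2 groups were fitted. A fit of only the 2 groups gave 1966 genes for 32 days against 10 days. With the length covariate the median log2 change of the 616 genes went from 0.50 (median SE 0.11) to 0.41 (SE 0.11).

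Single genes show the course in skin, although the files do not pair their IDs with names. ENSRNOG00000032728 rose from 28.6 ± 24.0 CPM (SD, n = 4) at 0 day to 1900 ± 262 CPM at 6 hours after paw incision, a log2 change of 6.30 (SE 0.54, adjusted p = 4.32e-07), and its log2 change of 0.56 at 10 days did not pass the test (adjusted p = 0.561). In SMIR skin the same gene rose by 4.98 (SE 1.39) at 6 hours, 8.57 at 2 days and 4.19 at 10 days, and its value of 2.60 at 32 days did not pass (adjusted p = 0.281). ENSRNOG00000042517 rose by 4.67 in both models at 6 hours (SE 0.56 in LPI and 1.21 in SMIR). ENSRNOG00000011161 fell by 3.67 in LPI (SE 0.45) and fell by 4.30 in SMIR (SE 0.31) at 6 hours. ENSRNOG00000047867 fell by 3.75 (SE 0.36) and fell by 3.50 (SE 0.24), and it had still fallen by 1.09 in SMIR skin at 10 days (adjusted p = 9.77e-04).

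The design's question of acute against chronic pain calls for a test of the difference between the changes. Site of incision, animals and any batch go with the model, so in no tissue can a called difference be assigned to the kind of pain. In skin that difference passed for 6662 genes at 6 hours, 3860 at 2 days and 2449 at 10 days. At 6 hours 380 genes rose in LPI and fell in SMIR, and 763 fell in LPI and rose in SMIR, with the difference itself called (394 and 745 under RLE scaling). At 10 days 2048 genes were called in SMIR alone and 26 in LPI alone, again with a called difference. Genes that had risen at least 2-fold in LPI skin at 2 days were also higher in SMIR skin at 2 days, with a median log2 change of 0.99 and 911 of 1476 called higher against 56 lower (adjusted p = 2.49e-09). At 10 days the same genes had a median of 0.32 in SMIR skin (423 higher, 122 lower, adjusted p = 8.13e-04), and at 32 days one of 0.17, which did not pass (adjusted p = 0.181). The 39 genes raised at least 2-fold in LPI skin at 10 days had a median of 1.27 in SMIR skin at 10 days, with 22 higher and 3 lower (adjusted p = 9.80e-05). Models shared 2721 higher and 2399 lower genes at 6 hours where independent lists would share 1409.76 and 1365.08.

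**Figure D1:**
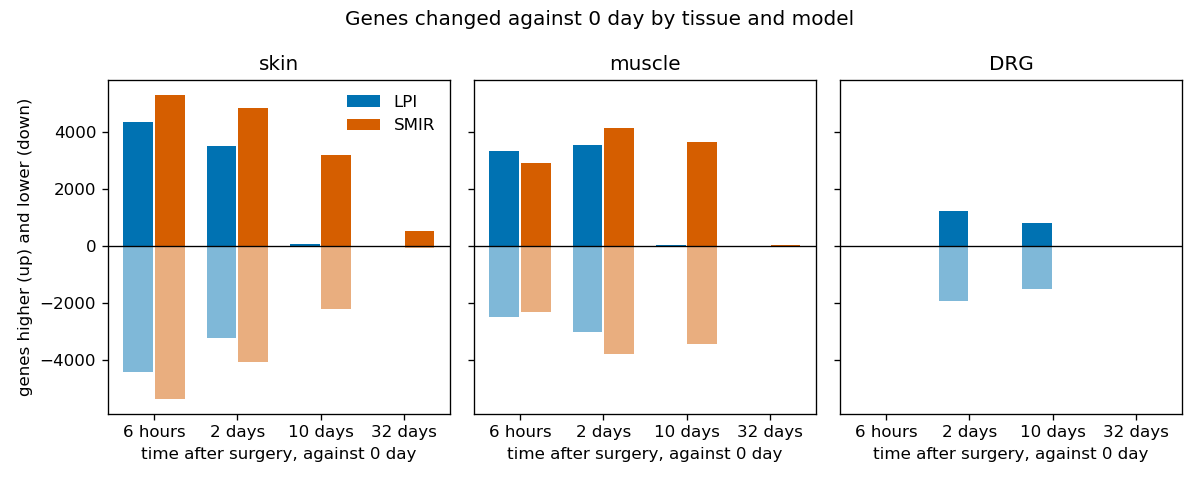
Numbers of genes called higher (upward bars) and lower (downward, paler bars) against 0 day at each time after surgery, for skin, muscle and DRG, in LPI (blue) and SMIR (orange); LPI has no 32-day group. SMIR skin and muscle still had 5428 and 7110 genes called at 10 days, where LPI had 93 and 52.

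In paw muscle 5839 genes changed at 6 hours and 6583 at 2 days, and most muscle-enriched genes were lower at 2 days. At 6 hours 3342 genes were higher and 2497 lower, and at 2 days 3544 higher and 3039 lower, with median absolute log2 changes of 1.20 and 1.29. At 2 days 155 of the 176 muscle-enriched genes were lower and 0 higher, with a median log2 change of −4.92, but the shift as a group did not pass fry (adjusted p = 0.321). Their share of counts was 7.20% ± 6.62 (SD, n = 4) at 0 day and 0.291% ± 0.266 at 2 days (exact permutation p = 0.0857), and at 0 day it ran from 0.175% in rat 1 to 16.1% in rat 4. DRG-enriched genes fell at 2 days (median −0.83, 52 higher and 137 lower of 518, adjusted p = 0.0247), but their share of counts was 0.978% ± 0.555 against 0.470% ± 0.0365 at 0 day (exact permutation p = 0.0857, adjusted 0.212), opposite in sign. Skin-enriched genes took 0.105% ± 0.0221 of counts at 0 day and 4.10% ± 2.70 at 2 days (exact p = 0.0286, adjusted 0.0923), and 190 of their 415 tested members were higher. At 10 days 28 genes were higher and 24 lower. That count of 52 was 0 without rat 1, 3 or 4 of 0 day or rat 4 or 6 of 10 days, 1 without rat 2 of 0 day, 3 without rat 5 and 129 without rat 7 of 10 days. It was 841 with DESeq2, 3 with no filter on low counts, 0 with the length covariate and 32 without the 6 genes that moved together. With the length covariate the median log2 change of the 52 genes went from 0.85 (median SE 0.16) to 0.72 (SE 0.22).

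In SMIR muscle 5235 genes changed at 6 hours, 7932 at 2 days and 7110 at 10 days, and most muscle-enriched genes were lower at 2 and 10 days. Of the genes tested, 2916 genes were higher and 2319 lower at 6 hours, 4138 higher and 3794 lower at 2 days, and 3660 higher and 3450 lower at 10 days, with median absolute log2 changes of 1.25, 1.41 and 1.30. Muscle-enriched genes fell at 2 days, with a median log2 change of −2.42, 127 of 176 lower and 1 higher (adjusted p = 0.0467, and 0.0514 with no filter on low counts). At 10 days 106 were lower and 2 higher, with a median of −1.78, which did not pass as a group (adjusted p = 0.0857). Their share of counts was 28.8% ± 1.33 (SD, n = 4) at 0 day, 9.43% ± 5.03 at 2 days and 12.0% ± 7.72 at 10 days, and both later values had an exact permutation p of 0.0286, 0.0923 after adjustment. With the same p values, the share of skin-enriched genes was 0.194% ± 0.0905 at 2 days and 0.158% ± 0.109 at 10 days against 0.0293% ± 0.00849 at 0 day, and that of DRG-enriched genes 1.148% ± 0.308 and 0.671% ± 0.293 against 0.237% ± 0.0135. DRG-enriched genes rose at 10 days (median 0.58, 118 higher and 36 lower of 565, adjusted p = 0.0345), although groups taken from LPI alone gave an adjusted p of 0.0837 and the length covariate 0.296. With that covariate the count of 7110 genes at 10 days was 3153. They fell between 10 and 32 days (median −0.40, 17 higher and 75 lower, adjusted p = 0.0345), with 0.0749 without the filter, 0.0655 with groups from LPI alone and 0.163 with the length covariate.

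By 32 days SMIR muscle had 12 genes higher and 2 lower than at 0 day, or 11 and 0 under RLE scaling and 17 and 10 with the length covariate. The share of muscle-enriched counts was 24.8% ± 10.2, and rat 3 stood apart at 9.96% where the other 3 libraries held at least 27.7%. The count of 14 was 0 without any of the 4 libraries of 0 day, and 37, 9 and 5 without rat 1, 3 or 5 of 32 days. DESeq2 called 463 genes, and a fit of the 2 groups alone called 0. From 10 to 32 days 2417 genes were higher and 2107 lower at 32 days, and 45 muscle-enriched genes were among the former and 2 among the latter (group adjusted p = 0.260). That count of 4524 was 2480 without rat 3 and 2631 without rat 6 of 10 days, 6793 without rat 3 and 2591 without rat 4 of 32 days, and 1899 in a fit of these groups alone. Simulated 2-fold changes at 32 days against 0 day were recovered for 17.9% of genes in this tissue and 4-fold changes for 63.6%, so smaller changes would mostly be missed.

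**Figure D2:**
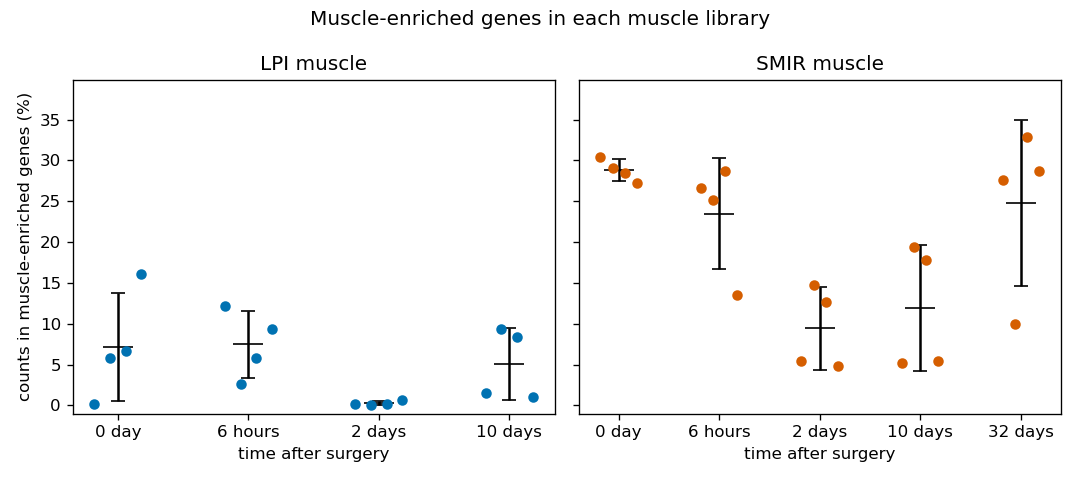
Percentage of counts in the 176 muscle-enriched genes in each muscle library by time after surgery, for LPI (left) and SMIR (right). Points are libraries, and horizontal marks with bars give the mean and SD of 4. All SMIR libraries of 2 and 10 days lie at or below 19.4%, and 1 library of 32 days lies at 9.96%.

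Many of the genes called in muscle were called in both models, and others in 1 model alone. Genes raised at least 2-fold in LPI muscle at 2 days had a median log2 change of 2.22 in SMIR muscle at 2 days, with 1464 of 1949 called higher and 18 lower (adjusted p = 4.43e-05). At 10 days in SMIR the same genes had a median of 1.54, with 1139 higher and 46 lower (adjusted p = 0.00234), and at 32 days the median of 0.43 did not pass (adjusted p = 0.516). Genes lowered in LPI muscle at 2 days had medians of −1.27 and −0.75 in SMIR muscle at 2 and 10 days (adjusted p = 3.01e-06 and 0.00171). At 2 days the models shared 2307 higher genes (66.7% of those of LPI) and 1657 lower genes (55.7%), where independent lists would share 887.13 and 700.84, and 78 genes rose in LPI and fell in SMIR and 66 fell in LPI and rose in SMIR with the difference called (70 and 69 under RLE scaling). Tissue shares also moved in both models at 2 days. Skin-enriched genes took 4.10% of counts in LPI muscle against 0.105% at 0 day, and 0.194% against 0.0293% in SMIR muscle. Muscle-enriched genes took 0.291% against 7.20% in LPI and 9.43% against 28.8% in SMIR. None of these shifts passed after adjustment. Whether they bear on the shared calls was not tested. The difference between the changes passed for 867 genes at 6 hours, 2252 at 2 days and 2533 at 10 days, and at 10 days 2325 genes were called in SMIR alone and 0 in LPI alone with that difference called. With the number of the column as a block, the counts for the difference were far lower, most of all at 10 days, as given below.

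Directions of the difference between models in muscle depended on scaling. At 6 hours 424 genes were higher in SMIR and 443 lower, but 572 and 255 without the 6 genes that moved together, whose share in LPI muscle was 6.71% ± 5.03 (SD, n = 4) at 0 day and 22.3% ± 9.61 at 6 hours (exact permutation p = 0.0571). At 2 days 920 were higher and 1332 lower, against 1164 and 1028 under RLE scaling, 1853 and 1543 with DESeq2 and 1305 and 817 without those genes. At 10 days 1348 were higher and 1185 lower, against 1656 and 913 without them. A fit of only the 4 groups compared gave 397 higher and 207 lower at 6 hours, 2084 and 1934 at 2 days and 2328 and 2002 at 10 days. RLE scaling put the median of all genes at 0.11 and 0.14 for SMIR muscle at 2 and 10 days, 0.15 for the difference at 2 days and −0.18 for the 0 day levels. DRG-enriched genes were higher in SMIR on balance at 2 days (41 higher, 11 lower of 630, adjusted p = 0.0467), with 0.164 without the filter and 0.0816 with the length covariate, which also gave 4355 genes for the difference at 10 days. The 6-hour count was 450, 487 and 544 without rat 1, 2 or 3 of LPI 0 day and 489 and 557 without rat 1 or 3 of SMIR 0 day, and 1658 with DESeq2. The 2-day count was 1372 and 1411 without rat 1 or 2 of LPI 0 day, 1413 without rat 5 of LPI 2 days, 1484 without rat 1 of SMIR 0 day, and 1436 and 1406 without rat 1 or 6 of SMIR 2 days, and 3396 with DESeq2. The 10-day count was 1585 without rat 1 of LPI 0 day, 1660 without rat 5 of LPI 10 days, 1614 without rat 1 of SMIR 0 day, and 1424 and 1615 without rat 3 or 6 of SMIR 10 days.

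In the DRG of LPI rats 1229 genes were higher and 1940 lower at 2 days, and 818 higher and 1511 lower at 10 days, with median absolute log2 changes of 0.52 and 0.53. Few were large: 181 were higher and 44 lower by at least 2-fold at 2 days. Of the 899 DRG-enriched genes 43 were higher and 100 lower at 2 days, which was not a shift as a group (adjusted p = 0.908). All 2-day and 10-day libraries had a positive gene-length trend (0.308 to 0.410 and 0.323 to 0.376), while 3 of the 4 libraries of 0 day had a negative one (lowest −0.512). With that trend as a covariate edgeR called 0 genes at either time. At 6 hours edgeR called 0 genes, with 1179 at an unadjusted p under 0.05 and 64 called by DESeq2. That count was 2, 1 and 8 without rat 1, 3 or 4 of 0 day and 15 without rat 4 of 6 hours. The 2-day count of 3169 was 343 and 1922 without rat 1 or 2 of 0 day, and 1859, 1983 and 0 without rat 1, 3 or 5 of 2 days. The 10-day count of 2329 was 0 without rat 1 or 3, 4 without rat 2 and 4363 without rat 4 of 0 day, 0 without rat 4, 5 or 6 and 4 without rat 7 of 10 days, and 3677 with DESeq2. Fits of only the 2 groups called 1659 and 5 genes at 2 and 10 days, and 0 genes were called at 10 days without the libraries above 1% of muscle-enriched counts.

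**Figure D3:**
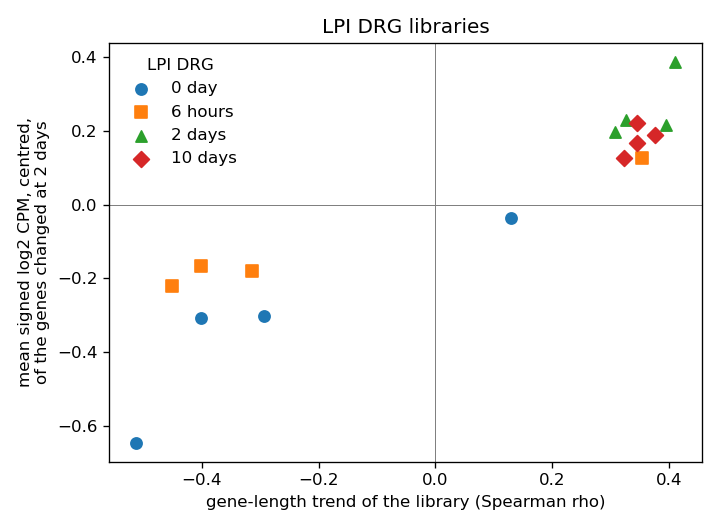
Each point is an LPI DRG library: its gene-length trend (Spearman's rho, horizontal) against the mean signed, centred log2 CPM of the genes called at 2 days (vertical), by time after surgery. The 6-hour library with a trend of 0.353 (rat 4) lies beside the 2-day and 10-day libraries, and the other 6-hour libraries lie between −0.451 and −0.314 on the horizontal axis. Both axes are computed from the log2 CPM of the same library, so they are not independent.

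In SMIR DRG edgeR called no gene, and DESeq2 called few. At 6 hours, 2 days, 10 days and 32 days against 0 day edgeR called 0 genes, with 1211, 1577, 1172 and 1602 at an unadjusted p under 0.05, and DESeq2 called 19, 10, 10 and 14. From 10 to 32 days it called 0, with 408 unadjusted and 8 by DESeq2. DRG-enriched genes had median log2 changes of 0.26, 0.35, 0.32 and 0.34 over the 4 times and muscle-enriched genes of −2.26, −6.68, −3.86 and −4.09, none of them passing as a group (lowest adjusted p = 0.366). Rat 4 of 0 day held 14.9% of its counts in muscle-enriched genes, against at most 2.00% in the other 19 SMIR DRG libraries, and without it 0 genes were called as well. The medians of both gene groups are against a 0 day group that includes this library. Its muscle-enriched genes had a median of 68.6 CPM, against 1.35 in the other 0 day libraries. The medians are therefore not read as a loss of muscle genes after SMIR. Genes raised in LPI DRG at 2 days had a median of −0.74 in SMIR DRG at 2 days, with 0 of 181 called (adjusted p = 0.566). That median is against a 0 day group with rat 4 in it and was not computed without this library. Over all genes called in LPI DRG at 2 days, the mean signed, centred log2 CPM was 0.265 in rat 4 of SMIR 0 day. It was −0.024, 0.144 and −0.062 in rats 1, 2 and 3 of that group. Simulated 2-fold changes were recovered for 41.8%, 38.8%, 37.3% and 25.4% of genes at the 4 times, so changes under that size would mostly be missed.

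The difference between models in DRG was called for 968 genes at 2 days (471 higher and 497 lower in SMIR) and for 2 genes at 10 days, whose IDs are not paired with names. At 6 hours edgeR called 0, with 1550 unadjusted and 27 by DESeq2. Of the muscle-enriched genes 42 of 172 were lower in SMIR at 2 days, beside the muscle share of rat 4 at SMIR 0 day. DESeq2 called 1829 genes at 2 days and 505 at 10 days (249 higher, 256 lower), and edgeR called 0 at both with the length trend as a covariate, and 0 at both in a fit of only the 4 groups compared. Without the DRG libraries above 1% of muscle-enriched counts the calls numbered 576 and 0, and with no filter on low counts 255 and 0. The 2-day count was 1, 215, 327 and 1912 without rat 1, 2, 3 or 4 of LPI 0 day, 165, 270, 617 and 0 without rat 1, 3, 4 or 5 of LPI 2 days, 2044 and 2108 without rat 1 or 3 of SMIR 0 day, and 0, 0, 161 and 1599 without rat 1, 3, 4 or 6 of SMIR 2 days. The 10-day count was 1, 0 and 632 without rat 1, 3 or 4 of LPI 0 day, 0 without any library of LPI 10 days, 395, 1, 459 and 0 without rat 1, 2, 3 or 4 of SMIR 0 day, and 4, 0 and 0 without rat 3, 5 or 6 of SMIR 10 days. The 6-hour count was 1 and 4 without rat 1 or 4 of LPI 0 day.

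Tissues of the same model shared changed genes to different degrees. In LPI at 6 hours skin and muscle shared 2477 higher and 1687 lower genes, where independent lists would share 926.77 and 656.80. Skin-enriched genes took 1.36% ± 2.04 (SD, n = 4) of counts in LPI muscle at 6 hours, with 4.396% in 1 library, against 0.105% ± 0.0221 at 0 day (exact permutation p = 0.0286, adjusted 0.0923), so skin RNA in muscle samples was not excluded as part of this overlap. In SMIR at 10 days skin and muscle shared 1337 and 618, against 681.29 and 426.80 (one-sided Fisher exact tests, adjusted p = 5.09e-197 and 1.02e-26). Genes are not independent replicates, and both tissues come from the same rats, so these p-values do not measure replication across animals. LPI skin and DRG at 2 days shared 166 higher and 200 lower genes, where independent lists would share 258.35 and 372.26, and 18 and 2 at a threshold of 2-fold, against 14.12 and 3.18. Overlaps smaller than those of independent lists were not tested. LPI muscle and DRG at 2 days shared 277 higher genes against 260.20 (Fisher exact, adjusted p = 0.148) and 470 lower genes against 364.46 (adjusted p = 1.46e-10). The DRG lists in these overlaps are those for which the length covariate left 0 calls.

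The models differed before surgery had acted. At 0 day 8977 genes in skin, 8190 in muscle and 3325 in DRG differed between SMIR and LPI rats. Skin-enriched genes took 22.8% ± 1.91 (SD, n = 4) of counts in LPI skin and 10.2% ± 0.480 in SMIR skin, and muscle-enriched genes 7.20% ± 6.62 in LPI muscle and 28.8% ± 1.33 in SMIR muscle. Site of incision, animals and any batch differ with the model and cannot be separated. The DRG count was 1002 without rat 1 and 2215 without rat 3 of LPI 0 day, and 0 when only the 2 groups were fitted.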

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

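All tests that weigh explanations in this part were chosen after the result was seen, while the tests of the difference between models had been fixed earlier. Bounds of 3 of them were also reset after their values were seen: the bound for an exchange of the SMIR DRG library with a muscle library, since under a first, lower bound that value decided nothing, and those for tissue admixture and for an injury response in the SMIR muscle library, since the first ones did not separate these explanations. In 81 tests for a library far from its group 3 were found. Chance flags about 1 in 20 such tests, so this number of flags is not beyond chance. The SMIR muscle library of rat 3 at 32 days, weighed below, is not among the 3 and did not pass that rule.

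In LPI DRG 3169 genes were called at 2 days and 2329 at 10 days, times at which every library had a positive gene-length trend. RNA of muscle in the ganglia is argued against at 2 days, since 0 of 149 muscle-enriched genes were called higher then and their share was at most 0.195% in a library, against at most 0.169% at 0 day. At 10 days it stays open: rat 6 held 1.27%, and 0 genes were called without it, but 0 were also called without rat 4 or 5 of that time. The length trend itself is a candidate explanation: the 6-hour library of rat 4, whose trend of 0.353 stood apart from the −0.451 to −0.314 of the other 6-hour libraries, lay 0.710 of the way from these to the 2-day libraries over the genes called at 2 days. Trend and score are both computed from the centred log2 CPM of a library. If the called genes differ in length from other genes, a positive trend brings a high score by construction. Neither this place nor the relation over the SMIR DRG libraries below can therefore separate the trend from another cause. With the trend as a covariate 0 genes were called, because folds shrank and not because errors grew: the median log2 change of the called genes went from 0.52 (median SE 0.14) to 0.14 (SE 0.15) at 2 days and from 0.53 (SE 0.14) to 0.12 (SE 0.14) at 10 days. A change in the ganglia after the incision and the trend cannot be told apart here, since time and trend go together, and over the 20 SMIR DRG libraries the relation of the trend with the score of these genes (Pearson's r 0.491, permutation p = 0.0266; Spearman's rho 0.550, permutation p = 0.0126; 1 relation computed) fell to r 0.307 and rho 0.418 without rat 1 of 6 hours and rat 4 of 10 days, the libraries farthest out in the trend. That loss appeared only while rat 4 of 0 day, weighed below for muscle RNA, was kept: without it r was 0.771 (permutation p = 1.20e-04) and rho 0.751 (permutation p = 3.10e-04), and without all 3 libraries r was 0.677 and rho 0.652.

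The SMIR DRG library of rat 4 at 0 day held 3.47% of its counts in DRG-enriched genes, where the other 3 libraries of the group held 18.2% to 20.9%, and 14.9% in muscle-enriched genes. An exchange with a muscle library is argued against, since the highest DRG-enriched share in a SMIR muscle library was 1.43%, far under the 14.7% of the lowest other DRG library. That this library hid a change in the ganglia is also argued against at the sizes detectable here, since 0 genes were called without it at each time. RNA of muscle in that library may explain its profile: across the muscle-enriched genes its CPM followed the SMIR muscle libraries of 0 day with Spearman's rho 0.961 (across genes, which are not independent replicates), and 175 of 176 members were higher than in the other 0 day libraries (median 68.6 CPM against 1.35, and 213 in muscle). How muscle RNA came into it stays open, and no biological explanation was tested.

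The SMIR muscle library of rat 3 at 32 days held 9.96% of its counts in muscle-enriched genes where the other 3 held at least 27.7%. An exchange with a muscle library of 2 or 10 days is argued against, since none of those exceeded 19.4%. Skin or ganglion tissue in an amount that would lower the muscle share to 9.96% is argued against. No SMIR muscle library of 32 days held over 0.325% of counts in skin-enriched or 0.454% in DRG-enriched genes. The mean skin-enriched share of SMIR skin at 0 day was 10.2%. SMIR DRG libraries other than rat 4 of 0 day held at least 14.7% in DRG-enriched genes. For genes that rise after injury, a smaller admixture and an injury response still present at 32 days cannot be told apart. Of the genes that rose at least 2-fold in LPI muscle at 2 days, 1949 were also tested in SMIR muscle. They lay 0.825 of the way from the other 32-day libraries to the 10-day libraries. But only 30 of these 1949 genes are no higher in SMIR skin or DRG than in the other 32-day muscle libraries. A smaller admixture would therefore raise most of the 1949 genes to some extent, by an amount that was not computed. Those 30 had a median log2 difference of −0.543 (quartiles −1.27 and 0.92), where 871 other genes no higher in these tissues had −1.33, so they were not raised but fell less, which decides for neither. Skin-enriched genes were higher in this library by a median of 2.52 and DRG-enriched genes by 0.65. Other tissues were not tested, and this is 1 library.

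The LPI skin library of rat 4 at 10 days had a gene-length trend of −0.110 where the others of its group had 0.181 to 0.230. The change after SMIR differed from that after LPI, by the test of the difference itself, for 6662, 3860 and 2449 genes in skin at 6 hours, 2 days and 10 days, for 867, 2252 and 2533 genes in muscle, and for 968 and 2 genes in DRG at 2 and 10 days. In DRG these calls depend on the fit, since edgeR called 0 at both times in a fit of only the 4 groups compared and 0 at both with the length trend as a covariate. The 2-day count was also 0 without rat 5 of LPI 2 days and without rat 1 or 3 of SMIR 2 days. The muscle counts moved with the fit as well. Leaving out each library in turn gave 450 to 1120 genes at 6 hours, 1372 to 2623 at 2 days and 1424 to 3247 at 10 days. With the number of the column as a block they were lower still, most of all at 10 days, as given below. The skin count at 10 days was also lower with that block.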

How the results depend on the processing

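The length covariate, the restrictions on DRG libraries, the removal of the 6 genes that move together the fit of only the 4 groups for the difference between models, the block of column numbers and all settings of the gene-group tests were chosen after seeing the data; the other settings were planned. RLE scaling kept all 36 counts within 1.5 times. Where a count moved, the cause was not tested unless stated. DESeq2 gave 1658 and 3396 for the muscle difference at 6 hours and 2 days, 27, 1829 and 505 for the DRG difference at 6 hours, 2 days and 10 days, 874 for LPI skin and 841 for LPI muscle at 10 days, 1302 for SMIR skin and 463 for SMIR muscle at 32 days, 19, 10, 10, 14 and 8 for SMIR DRG in time order and then 32 against 10 days, and 64 and 3677 for LPI DRG at 6 hours and 10 days. No filter on low counts gave 255 and 0 for the DRG difference at 2 and 10 days, 350 for SMIR skin at 32 days, 56 for LPI skin and 3 for LPI muscle at 10 days. Fitting only the 2 groups, with fewer samples, gave 0 for DRG at 0 day, 0 for SMIR skin and 0 for SMIR muscle at 32 days, 1966 and 1899 for these tissues at 32 against 10 days, 2 for LPI skin at 10 days, and 1659 and 5 for LPI DRG at 2 and 10 days. Fitting only the 4 groups gave 4018 and 4330 for the muscle difference and 0 and 0 for the DRG difference at 2 and 10 days. The length covariate gave 3, 0 and 0 for LPI DRG in time order and 0 and 0 for the DRG difference at 2 and 10 days, 4167 and 213 for LPI skin at 2 and 10 days, 462 and 113 for SMIR skin at 2 and 32 days, 0 for LPI muscle at 10 days, 3153 and 27 for SMIR muscle at 10 and 32 days and 4355 for the muscle difference at 10 days. At 10 days in SMIR muscle the median log2 change of the called genes went from 1.30 (SE 0.33) to 0.70 (SE 0.27). Only libraries with a positive trend gave 19, 7 and 6 for LPI DRG, where 6 hours and 0 day had 1 library each, whose spread was assumed to be that of the 2-day and 10-day groups, so that the first count sets 1 library against 1. Leaving out DRG libraries above 1% of muscle-enriched counts gave 576 and 0 for the DRG difference at 2 and 10 days and 0 for LPI DRG at 10 days. Removing the genes that move together gave 32 for LPI muscle at 10 days. At a threshold of 2-fold 1 lower gene was shared by LPI and SMIR skin at 10 days, no longer beyond independent lists, as were 8 lower genes in LPI muscle and DRG at 2 days and 0 higher and 0 lower at 10 days, while 44 higher genes of LPI muscle and DRG at 2 days and 2 higher genes of SMIR skin and muscle at 32 days then passed.

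Leaving out each library gave these ranges. The muscle difference ran from 450 (without rat 1 of LPI 0 day) to 1120 at 6 hours, from 1372 to 2623 at 2 days and from 1424 to 3247 at 10 days. The DRG difference ran from 0 to 4, from 0 to 2108 and from 0 to 632, and the DRG difference at 0 day from 1002 to 4354. SMIR skin at 32 days ran from 86 to 1425, LPI skin at 10 days from 0 to 652, SMIR muscle at 32 days from 0 to 37 and against 10 days from 2480 to 6793, and LPI muscle at 10 days from 0 to 129. LPI DRG ran from 0 to 15 at 6 hours, from 0 (without rat 5 of 2 days) to 4681 at 2 days and from 0 to 4363 at 10 days. Of the gene-group tests that passed, 46 also passed without the filter and 50 with RLE scaling, and 4 and 0 did not; with groups from the other model alone 6 passed and 2 did not, with the length covariate 4 of the tissue-enriched tests passed and 5 did not, and all 4 tests rerun without rat 4 of SMIR DRG at 0 day and rat 3 of SMIR muscle at 32 days passed. The planned replicate block of the labels' numbers was not run, since columns could not be matched to single labels. The numbers of the columns recur in part between time points, but libraries of 1 number at 2 times deviated together (r over 0.1 across genes) in 28 of 129 pairs, against 161 of 639 pairs of other numbers. By this count libraries of 1 number were no closer than others. The pairs overlap and are not independent, so a batch shared behind a number is not excluded. With that number as a block the difference between models gave 1146 for skin at 10 days, 174, 498 and 36 for muscle and 0 and 0 for DRG at 2 and 10 days. Against 0 day it gave 61 for LPI skin at 10 days, 3676 and 4 for LPI muscle and 0 and 0 for LPI DRG at 2 and 10 days, 187 for SMIR skin at 32 days, and 3750 and 1 for SMIR muscle at 10 and 32 days, and 1963 for SMIR muscle at 32 against 10 days. Levels at 0 day were not fitted with it, and it moved no other count by over 1.5 times. The planned gene list tests and the rule for named genes were not run either, since IDs are not paired with names. Simulated 1.5-fold changes against 0 day were recovered for 0% of genes at each time in LPI muscle, 1.49% to 7.46% in SMIR muscle, 5.97% to 8.96% in SMIR DRG, 28.4% to 38.8% in LPI DRG and 11.9% to 23.9% in skin. Depth as a reason was not tested.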

Other observations

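The gene-group readings and the counts of splits in this part were chosen after the result was seen, and the 36 comparisons they bear on were planned. Genes raised at least 2-fold in LPI skin at 6 hours were higher in SMIR muscle at 6 hours, with a median log2 change of 1.43 and 1044 of 1706 called higher against 15 lower (adjusted p = 2.11e-07). Skin-enriched genes also took more of the counts in that muscle, 0.186% ± 0.149 (SD, n = 4) against 0.0293% ± 0.00849 at 0 day (exact permutation p = 0.0286, adjusted 0.0923). Of the 1569 genes lowered at least 2-fold in LPI muscle at 6 hours, 1523 were also tested in SMIR muscle. These 1523 had a median of −0.93 in SMIR muscle at 6 hours, when 609 were called lower and 16 higher, and of 0.78 at 10 days, when 523 were higher and 101 lower (adjusted p = 0.00803). Of them 131 were called lower at 6 hours and higher at 10 days, and 84 lower at both times. Tissue shares of SMIR muscle moved at 10 days too: muscle-enriched genes took 12.0% against 28.8% at 0 day. DRG-enriched genes took 0.671% against 0.237% and skin-enriched genes 0.158% against 0.0293%. Whether these shares bear on the rise was not tested. Across genes, which are not independent replicates, the changes of the models correlated with Spearman's rho 0.43, 0.53 and 0.19 in skin at 6 hours, 2 days and 10 days, 0.59, 0.63 and 0.39 in muscle, and −0.13, −0.17 and −0.10 in DRG. The SMIR changes in DRG are against a 0 day group that includes rat 4, weighed above for muscle RNA. The DRG correlations were not computed without that library, so their sign is not read as an opposite response.

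Splits of the same libraries into groups of the same sizes, 35 for each pair of groups with the real one among them, were fitted on these libraries alone. Counts of splits that gave at least as many genes include the real one. Chance is argued against for LPI skin at 6 hours (8655 genes in the real split, at most 1 in another) and 2 days (7048, 1), for SMIR skin at 6 hours (11176, 2), 2 days (9321, 1), 10 days (6815, 3) and 32 against 10 days (1966, 1), for LPI muscle at 6 hours (5343, 1) and 2 days (5482, 1), for SMIR muscle at 6 hours (4173, 0), 2 days (9650, 0) and 10 days (8468, 1), and for the levels at 0 day in skin (9878, 1) and muscle (9159, 1), since in each of these the real split was alone on top and gave far more genes than any other. A real split alone on top is the lowest count that 35 splits can give, so this count by itself does not exclude chance. The real split was also alone on top in LPI muscle at 10 days (73 genes, highest other 2) and LPI DRG at 2 days (1659, 3). Over the 27 such comparisons, however, chance alone would give about 0.771 with the real split on top. The full fit's count of 52 in that muscle was at most 3 without any 1 of 7 of the 8 libraries, and that of 3169 in DRG was 343 without rat 1 of 0 day, 0 without rat 5 of 2 days and 0 with the length trend as a covariate, so both results stay weak. Chance cannot be excluded for LPI skin at 10 days, where 3 of 35 splits gave at least the real 2 genes and another gave 81, nor for LPI DRG at 10 days, where 2 gave at least the real 5 and the other gave 149. The first of these put rat 4 of 10 days with rats 1, 2 and 4 of 0 day. The second exchanged rat 4 of 0 day for rat 7 of 10 days, libraries with positive length trends of 0.129 and 0.323. What sets these splits apart was not tested. Chance cannot be excluded either for SMIR muscle at 32 against 10 days, where 2 splits gave at least the real 1899 and the other gave 3282. That split put rats 3, 5 and 6 of 10 days with rat 3 of 32 days, and what sets it apart was not tested. Where the real split gave 0 genes all 35 gave as many: SMIR skin at 32 days (highest other 1), SMIR muscle at 32 days (1), LPI DRG at 6 hours (6), SMIR DRG at 6 hours (0), 2 days (1), 10 days (1), 32 days (1) and 32 against 10 days (4), and DRG at 0 day (1).

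For the differences between models 40 splits were taken, the real one among them, exchanging times within models and fitting the 4 groups compared alone. The counts of splits below include the real one. Exchanged times mix the time effects of a model or turn their sign, so these counts do not test whether the models differ. In skin 1 split gave as many at 6 hours (7240 genes in the real split, highest other 5290), 2 at 2 days (4780, 5256) and 1 at 10 days (3215, 2438), and in muscle 1 at 6 hours (604, 176), 2 at 2 days (4018, 4775) and 2 at 10 days (4330, 4719). In DRG all 40 gave at least the real 0 at 6 hours, 2 days and 10 days, with 1 as the highest other at each time.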
